A study of Mus musculus with 6 samples.

How the data were processed

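Gene expression was measured on mouse oligonucleotide arrays in 6 samples labelled as single embryonic hearts, 3 Sp3 knockout and 3 wildtype. The stage was given as E12.5. Groups and letters were taken from the sample titles. The submitters' processing notes name GCOS and RMA, with no version or role given in the sources used here. The deposited values are intensities on a linear scale, between 0.0562 and 12897, and which of these tools made them is not known. Array medians ran from 22.6 to 26.8 and 75th percentiles from 107.6 to 124.5, so the arrays do not share 1 distribution of values. Per the labels, RNA came from single hearts and was labelled in 1 cycle.

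The design had assumed log2 values. Since the deposited table was linear, log2 was taken first and no other normalization was applied. The group medians of log2 values differed by 0.08. No array pair held the same values beyond 1 probe set, so no array was a copy of another. Per the labels of single hearts, each array was taken as 1 replicate. Identical values cannot show whether the samples are independent. The p-values measure the spread between these samples, and the number of arrays limits their precision. Annotation gave 1 gene for 34945 probe sets, several for 932 and none for 9160. Symbols were checked against GRCm38.p6 through gene identifiers, of which 34741 matched, and 0 changed. A gene was represented by its probe set of highest mean, which gave 18193 genes.

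Tests were run in R 4.3.3 with limma 3.58.1. The main test was lmFit and eBayes on log2 values with group as the only term, on 45037 probe sets with no filter, two-sided, with Benjamini-Hochberg adjusted p under 0.05. The 64 control probe sets were left out. Gene lists were fixed before the data were examined, 30 in all, of which 29 were tested with camera and 1, the embryo sex markers, was kept as a check. The list of genes reported as repressed by SUMO-modified Sp3 came from knowledge of published work, and Ankrd1 was placed in the cardiac stress list partly because the study's own paper is remembered to have followed it up, so neither is independent evidence. Genes were named by a rule set at the same time: Sp3, the 12 genes of largest change per direction among those passing with no overlap, filled by smallest unadjusted p, the leading members of each list, the brightest members of cell type lists, Ankrd1 and the sex markers. The levels of marker lists were set against all genes as percentiles, a step chosen after the data were seen.

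Alternatives were quantile normalization, median centring, leaving out dim probe sets, eBayes with a trend and robust estimation, array weights, the letter as a block, the Xist level as a covariate, each array left out, a fold of at least 1.5, counting genes, and for lists an estimated correlation, fry and the mean of a gene's probe sets. For genes near Sp3 the called genes were those of the fit with 1 probe set per gene. Adding 16 intensity units before log2, other rules for a called gene near Sp3, the interferon list level as a covariate and each alternative on top of the trend fit were added after the data were seen. The tests were run on simulated data with 200 of 45037 probe sets changed, all drawn from those above the median level. The simulated spreads followed intensity, as the trend fit assumes. The recovery therefore does not cover dimmer probe sets, and the setting favours the trend fit. At a log2 change of 1 the fit without the trend recovered 0% and the trend fit 14%, with 0 and 1 unchanged probe sets called, and at a log2 change of 2 they recovered 40% and 77%, with 4 and 8 unchanged probe sets called. No coordinates are given, because the files name no genome build.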

Results

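Per the labels, the series set samples labelled as embryonic hearts of mice that lack Sp3, a zinc finger transcription factor that binds GC-rich promoter elements, against samples labelled as wildtype hearts, at stage E12.5. Each sample was labelled as the total RNA of a single heart, marked with biotin and hybridised to 1 oligonucleotide array. There were 3 Sp3 knockout arrays and 3 wildtype arrays, each set lettered a to c. The median intensity per array lay between 22.6 in wildtype b and 26.8 in wildtype c, and 45037 probe sets other than controls were tested. The number of arrays limits the precision of every value.

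Liver and red cell transcripts lay near the top of the scale in all 6 arrays labelled heart, and most contractile transcripts of heart muscle below the middle. Over the 16 measured genes of a liver list the median level was 11.3 on the log2 scale, the 98.3th percentile of the 18193 genes, and no array lay below the 97.9th percentile. Alb, serum albumin, was at 13.16 ± 0.12 in knockout and 13.34 ± 0.07 in wildtype (SD, n = 3 each). Afp, alpha-fetoprotein, was at 13.28 ± 0.06 in knockout and 13.28 ± 0.03 in wildtype. The erythroid list had a median of 11.09, with Klf1, a regulator of red cell genes, at 11.76 ± 0.39 and 12.04 ± 0.12. The sarcomere list, the contractile proteins of muscle, had a median of 4.39, the 39.1th percentile, and 22 of its 27 genes lay below the 50th percentile. Myh6, a cardiac myosin heavy chain, was at 2.92 ± 0.48 in knockout and 0.91 ± 0.85 in wildtype, and Nppa, the atrial natriuretic peptide, at 3.32 ± 0.59 and 3.78 ± 0.37. Actc1, cardiac actin, at 8.69 ± 0.40 and 7.61 ± 1.21, and Myl7, an atrial myosin light chain, at 7.54 ± 0.48 and 6.85 ± 0.47, were higher up the scale, as was Tpm1, a tropomyosin, at 9.42 ± 0.18 and 9.48 ± 0.19. The cardiac transcription factor list had its median at the 49.9th percentile, and 14 of its 27 genes lay below the 50th. Of its members, Mef2c lay at the 83.1th percentile, Hand2 at the 80.7th and Gata6 at the 78.8th. Nkx2-5 lay at the 29.8th, Tbx5 at the 25.8th and Irx4 at the 6.54th. These members were picked after their values were seen. Levels of different probe sets also depend on their sequences, so the percentiles describe whole lists, and no heart or liver array was analysed here for comparison.

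**Figure D1:**
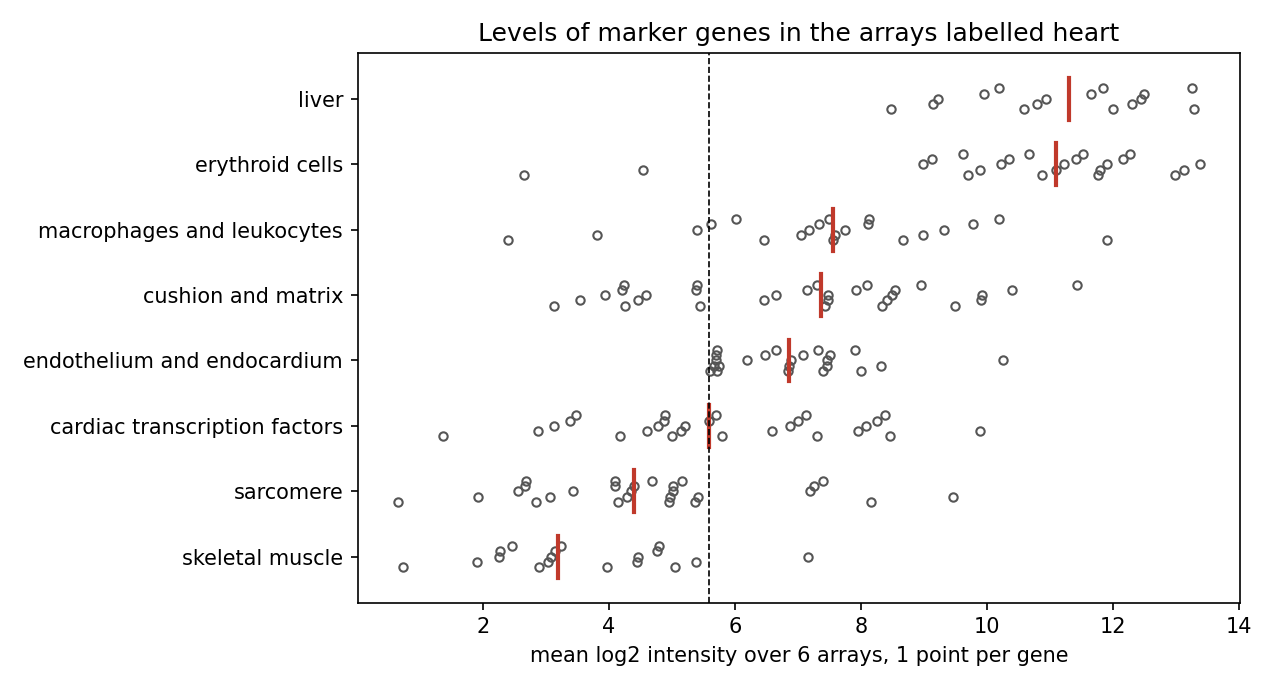
Mean log2 intensity over the 6 arrays of each gene in 8 marker lists, 1 point per gene; the red bar is the list median and the dashed line the median of all genes at 5.59. The liver list centres on 11.3 and the sarcomere list on 4.39.

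The single Sp3 probe set was lower in the knockout arrays, at 8.45 ± 0.14 against 9.72 ± 0.17 in wildtype (SD, n = 3 each), a log2 difference of -1.27. The 3 knockout arrays, at 8.39, 8.34 and 8.61, all lay below the 3 wildtype arrays, at 9.87, 9.77 and 9.54. The limma adjusted p was 0.279 without an intensity trend and 0.00254 with one, and with the trend it ranged from 0.000533 to 0.0665 over the alternatives. The highest was the fit without knockout a, the only one of these in which the call was lost. Where this probe set lies against the deleted part of the gene is not given in the sources used here, so it reads only its own part of the transcript.

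Across all probe sets, limma without an intensity trend called 0 probe sets higher and 0 lower in knockout at an adjusted p under 0.05. The smallest adjusted p was 0.139, and 2699 probe sets, 5.99%, had an unadjusted p under 0.05. The median residual SD was 1.27 in the dimmest of 10 classes of probe sets by level and 0.125 in the brightest. With a variance trend over intensity and robust estimation, an alternative listed before the data were examined, limma called 7 probe sets higher and 7 lower. The lead given to this fit was chosen after the data were seen. It had 3225 probe sets, 7.16%, with an unadjusted p under 0.05. The groups did not overlap in 5873 probe sets, of which 2769 were higher and 3104 lower in knockout, 13.04% in all where chance gives 10%.

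With the trend, the probe sets higher in knockout belonged to Rbm45, Itga4, Pnliprp2, Tcfl5 and Dmc1. Rbm45, an RNA-binding protein, was at 9.26 ± 0.05 in knockout and 6.41 ± 0.50 in wildtype, with limma adjusted p = 0.000328. A probe set of Itga4, the integrin alpha 4 chain, was at 9.92 ± 0.02 and 8.10 ± 0.29, with the same adjusted p. Dmc1, the meiotic recombinase, rose at both of its probe sets. At 1 of them it rose by 2.39 on the log2 scale, with adjusted p = 0.0139, and the difference was 1.66 with 16 intensity units added before log2, a setting chosen after the data were seen. The other was at 6.40 ± 0.14 in knockout and 0.42 ± 1.16 in wildtype, a level within the dimmest class of probe sets, with adjusted p = 0.00962. Its difference of 5.99 is therefore not an exact size, and it was 2.52 with the units added. Pnliprp2, a pancreatic lipase-related protein, rose by 2.35 and 2.29 at its 2 called probe sets, and Tcfl5, a transcription factor of the germline, by 2.62. Lower in knockout, besides Sp3, were Ifi30, a lysosomal thiol reductase, at -1.15, Ptgr1, a prostaglandin reductase, at -1.29, a probe set of Itga6, the integrin alpha 6 chain, at -1.15, Rnh1, the ribonuclease inhibitor, at -0.82, Zdhhc2, a palmitoyltransferase, at -1.77, and a probe set annotated to several genes at -0.97. Rbm45, the Itga4 probe set and 1 Pnliprp2 probe set passed in each of the 6 fits that left out an array. Rnh1 and Zdhhc2 passed in none of them, while their log2 differences stayed between -0.88 and -0.76 and between -1.88 and -1.63. All 4 probe sets of Zdhhc2 were lower in knockout with no overlap. The Dmc1 probe set that rose by 2.39 passed in 2 of these 6 fits and the other in 3. The trend fit called 3 higher and 0 lower without knockout a, 3 and 4 without knockout c, and 12 and 12 without wildtype c. It called 1 lower without wildtype a and 4 lower without wildtype b. These genes were named after their values were seen, apart from those that the naming rule also picks.

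**Figure D2:**
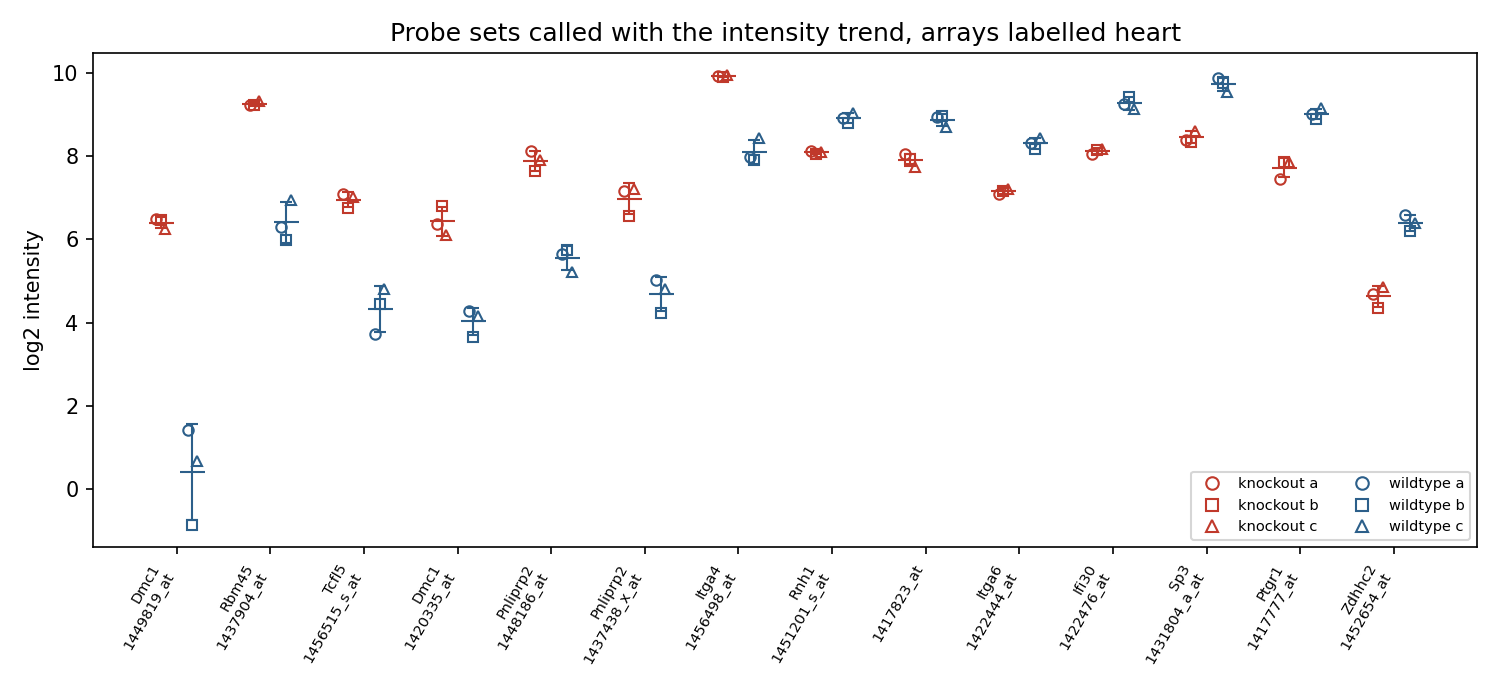
Log2 intensity per array of the 14 probe sets called with the intensity trend, with the mean and SD of each group (n = 3). The groups do not overlap at any of them.

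The naming rule filled its places with genes of smallest unadjusted p, since none passed without the trend. In the higher direction these were Mageb3, Cxcr6, Cyp2b19, Cmtm2b, Pnliprp2, Rbm45, Cypt12 and Amer2, and 4 genes with clone names. Their log2 differences lay between 1.31 and 3.71 and their limma adjusted p without the trend between 0.139 and 0.201. With the trend Pnliprp2 and Rbm45 passed, and the others had a limma adjusted p between 0.418 and 0.762. In the lower direction they were Mospd4, Grm2, Lax1, Ccdc175, Adgrv1, Gzma, Zdhhc2, Elapor2, Gpat2 and Mroh3, and 2 genes with names of predicted transcripts, with adjusted p between 0.139 and 0.225 without the trend. With the trend Zdhhc2 passed, and the others had a limma adjusted p between 0.246 and 0.665. Of the 12 in each direction, 10 and 11 lay below the median level of all probe sets. In 9 and 7 of them the lower group lay within the dimmest class of probe sets, so the sizes of their differences are not exact. The knockout levels of Mospd4, Grm2, Gzma and Mroh3 lay in the class next to the dimmest, so their sizes are not exact either.

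Of 29 gene lists, limma camera with a preset correlation of 0.01 called 14, of which 8 were shifted up and 6 down in knockout. Hypoxia and glycolysis, sarcomere, signalling in heart development, and macrophages and leukocytes were the 4 called in each of the 6 fits that left out an array. With an estimated correlation camera called 0, with 0 at an unadjusted p under 0.05 and a smallest adjusted p of 0.422, and fry called 0. Without knockout c, 7 lists were called. Quantile normalization left 7 shifted up and 1 down. Of the 677 genes in the lists, 35 had an unadjusted p under 0.05 in limma without the trend, 0 passed, and 1, Dmc1, passed with it.

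Lists shifted up were led by hypoxia and glycolysis, with 23 of 26 genes higher, a median log2 difference of 0.46 and camera adjusted p = 7.08e-06. The adjusted p was 0.478 with an estimated correlation. Vegfa, a vascular growth factor, differed by 0.81 and Car9, a carbonic anhydrase, by 0.83, neither passing over all genes. Adjusted over the list alone, 2 of its genes passed with the trend. The list level overlapped between the groups, at 0.28, -0.14 and 0.54 in knockout a, b and c and -0.31, -0.02 and -0.27 in wildtype. The sarcomere list had 23 of 27 genes higher, a median of 0.70 and camera adjusted p = 6.85e-05, with an adjusted p of 0.422 under an estimated correlation. Myl3, a myosin light chain, differed by 1.27, and most of the list's genes lay below the median level of all genes. For Myh6 no size of the difference is given, since its wildtype level lies within the dimmest class of probe sets. Of its genes 0 passed, also when adjusted over the list alone. Its level was 0.32, 0.40 and 0.31 in knockout and 0.25, -0.71 and -0.29 in wildtype, and its median difference was 0.23 without wildtype b. That of hypoxia and glycolysis was 0.27 without knockout c.

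Lists of heart regulators, in arrays whose tissue is not settled, were also shifted up. Cardiac transcription factors had 22 of 27 genes higher, with Gata5 at 0.46 and Foxc2 at 1.14, and signalling in heart development 28 of 35, with Bmp2 at 0.59. Immediate early genes had 15 of 20 higher, with Nr4a2 at 0.97 and Ccn1 at 0.79. Among markers of other cells, cushion and matrix genes were higher in 25 of 30, with Hapln1 at 0.59 and Papss2 at -0.73. Neural and neural crest genes were higher in 13 of 18, and skeletal muscle genes in 14 of 18, with Myog at 1.53. Tfap2b, of the neural list, was at 3.86 ± 0.21 in knockout and 1.92 ± 0.64 in wildtype. Its wildtype level lies in the class next to the dimmest, with a median residual SD of 1.39, so this size is not exact either. Bmp10, of the signalling list, was at 1.85 ± 0.69 in knockout and 0.60 ± 0.21 in wildtype, and Myf6, of the skeletal muscle list, at 1.52 ± 1.01 and -0.04 ± 0.29. Both wildtype levels lie within the dimmest class of probe sets, so the sizes of these differences are not exact. The level of the neural list was 0.25, 0.29 and 0.63 in knockout a, b and c and -0.04, -0.85 and 0.32 in wildtype a, b and c. Levels also overlapped between the groups for the cardiac transcription factor, signalling, cushion and skeletal muscle lists. Camera adjusted p for these 6 lists lay between 0.00362 and 0.0144, and with an estimated correlation the adjusted p lay between 0.422 and 0.541. No member passed over all genes, and adjusted over the list alone 1 neural gene, Tfap2b, passed without the trend and not with it. Without wildtype b the median log2 difference went from 0.60 to 0.20 for neural genes, from 0.18 to 0.07 for cushion genes, from 0.30 to 0.11 for cardiac transcription factors, from 0.22 to 0.14 for signalling and from 0.32 to 0.19 for immediate early genes. Without knockout c it was 0.23 for neural genes, 0.16 for cardiac transcription factors and 0.12 for signalling. For cushion genes it was 0.29 without wildtype a and 0.32 without wildtype c, and for skeletal muscle genes it went from 0.59 to 0.98 without wildtype a. Camera adjusted p rose to 0.160 for cushion and 0.113 for skeletal muscle genes without knockout a, and to 0.0575 for cardiac transcription factors and 0.0579 for neural genes without knockout c. It was 0.0844 for neural genes without wildtype a, 0.425 for cushion and 0.0534 for neural genes without wildtype b, and 0.0873 for skeletal muscle and 0.110 for immediate early genes without wildtype c. Wildtype b had the lowest level of the 6 arrays on the cardiac transcription factor, signalling and cushion lists, at -0.31, -0.24 and -0.36. It was also lowest on the neural, skeletal muscle and sarcomere lists. The same held for the uncalled foregut and lung and calcium handling lists, at -0.54 and -0.47. On the immediate early and hypoxia lists another wildtype array was lowest. The lists with wildtype b lowest are thus not independent results.

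Lists shifted down held leukocyte, erythroid and metabolic genes. Their median levels were high, between the 72.4th and 98.0th percentile of all genes. Those of the lists shifted up lay between the 26.6th and 69.9th, apart from hypoxia and glycolysis at the 85.4th. The median log2 value over all probe sets was 4.69 in knockout and 4.62 in wildtype. After quantile normalization 1 list was called as shifted down. Whether the distribution of levels per array accounts for these shifts was not tested. Macrophages and leukocytes had 18 of 21 genes lower and a median of -0.41, with C1qb, a complement chain, at -0.75 and Ptprc, the CD45 antigen, at -0.68. Adjusted over the list alone, 6 of its genes passed with the trend. Its level was -0.64 in knockout c, -0.05 and -0.04 in knockout a and b, and 0.09 to 0.36 in wildtype, and its median was -0.25 without knockout c. Fatty acid oxidation had 14 of 20 genes lower, with the acyl-CoA dehydrogenases Acadm at -0.40 and Acadl at -0.43, and 7 passed with the trend when adjusted over the list alone. Cell cycle genes were lower in 23 of 30, with Rrm2, a subunit of ribonucleotide reductase, at -0.37. Erythroid genes were lower in 20 of 23, with Trim10 at -0.75 and Epb42 at -0.59, which were at -0.31 and -0.26 without knockout c. The level of the erythroid list was -0.60 in knockout c, -0.03 and 0.18 in knockout a and b, and 0.22, 0.26 and -0.01 in wildtype, and its median difference of -0.28 was -0.06 without knockout c and -0.43 without knockout b. Sterol synthesis genes were lower in 14 of 16, with Sc5d at -0.39. Oxidative phosphorylation genes were lower in 63 of 80, although the members of smallest p, Cox6a2 at 0.89 and Cox8c at 0.73, were higher. Camera adjusted p for these 6 lists ran from 0.00125 to 0.0178, and with an estimated correlation the adjusted p ran from 0.422 to 0.624. Without knockout c only the leukocyte list kept its call, and camera adjusted p was 0.538 for erythroid, 0.0625 for cell cycle, 0.0974 for sterol and 0.0579 for the remaining lists. The medians of the cell cycle, sterol, fatty acid and oxidative phosphorylation lists were -0.11, -0.15, -0.22 and -0.09 in that fit, against -0.17, -0.16, -0.18 and -0.10 over all arrays. It was 0.113 for oxidative phosphorylation without knockout a, and 0.0632 for fatty acid and 0.0536 for sterol genes without knockout b. Sterol genes were at 0.0927 without wildtype a, and erythroid genes at 0.230 and fatty acid genes at 0.181 without wildtype b.

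**Figure D3:**
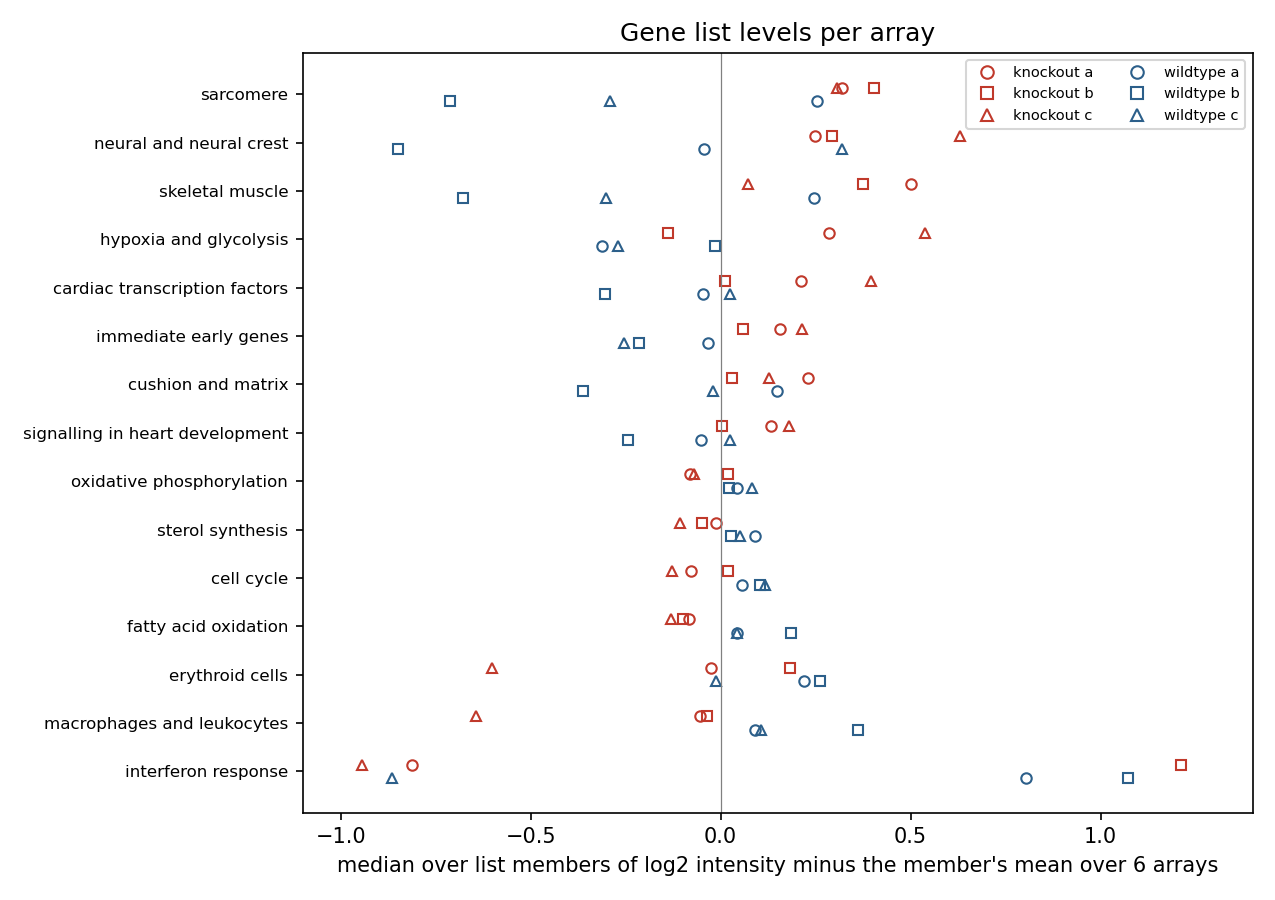
Level of the 14 called lists and of the interferon response list per array, as the median over members of log2 intensity minus each member's mean over the 6 arrays. The interferon list lies at 1.21 in knockout b and at -0.87 in wildtype c.

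The other 15 lists were not called. These were cardiac stress genes, calcium handling and conduction, endothelium and endocardium, epicardium, smooth muscle, foregut and lung, liver, p53 targets, ribosomal proteins, the unfolded protein response, interferon response, Sp and Klf factors, genes reported as repressed by SUMO-modified Sp3, germline genes and imprinted genes, with camera adjusted p from 0.0744 to 0.881. For p53 targets, ribosomal proteins and germline genes the median was below 0 while camera gave a shift up. Adjusted over the list alone with the trend, 1 smooth muscle gene was higher, 1 epicardial gene lower, and Dmc1 higher in both lists that hold it. The interferon list, with 17 of 20 genes lower, was called without knockout b at camera adjusted p = 0.00018 and without wildtype c at 0.00128, and the liver list without wildtype c at 0.00625. The SUMO-modified Sp3 list was called without knockout b at 0.0462, without wildtype a at 0.018 and without wildtype b at 0.0272. Without knockout b foregut and lung genes were at 0.0302 and imprinted genes at 0.0453. Without wildtype a calcium handling genes were at 0.032, epicardial genes at 0.017 and smooth muscle genes at 0.0386. These calls used the preset correlation. With an estimated correlation, over all 6 arrays, the adjusted p was 0.715 for the interferon list and 0.422 to 0.760 for the other lists called here when an array was left out. Of the 5 measured genes of the SUMO-modified Sp3 list, 4 were higher and Dmc1 passed with the trend. All 5 lay below the 50th percentile of all genes. Robo3 differed by 1.27 at 1 probe set and -0.99 at the other, Dnah8 by 0.70 and 0.10, and Paqr6 by 0.11. The list was drawn from published work on Sp3 and is not independent evidence. Ankrd1, a cardiac ankyrin repeat protein, was at 4.39 ± 0.69 in knockout and 1.49 ± 1.52 in wildtype at 1 probe set, with limma adjusted p = 0.742, and at 4.52 ± 0.90 and 3.68 ± 0.92 at the other, with 0.863.

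Genes near Sp3 were examined because a targeted allele carries the genome of the cells in which it was made. Gene order came from GRCm38.p6. Among the 100 annotated genes on either side of Sp3, 82 were measured, and 0 were called without the trend, so that the planned test could not be made. With the trend and 1 probe set per gene, 1 of the 82, Rbm45, was called, against 13 of 18110 elsewhere, which did not pass (two-sided Fisher's exact p = 0.0613, odds ratio 17.2, 95% interval 0.4 to 117). Counting a gene as called when any of its probe sets was called, a rule chosen after the data were seen, gave 2 of the 82, Rbm45 and Itga6, against 8 elsewhere (Fisher's exact p = 0.000882, odds ratio 56.4). Itga4 lies outside this window and inside that of 200 genes, so it counts among the 8 elsewhere under that rule. The log2 differences of the other probe sets above the median level lay between -0.45 and 0.35 for Itga4 and at -0.06 for Itga6. Itga6 was called in 3 of the 6 fits that left out an array, and its limma adjusted p was 0.191 without knockout a. Some genes closer to Sp3 also lay lower in knockout without passing. Gpr155 differed by -1.28, Ola1 by -0.41 and -0.51 at its brightest probe sets, and Scrn3 by -0.66 to -0.47. Cir1, between Ola1 and Scrn3, differed by -0.03, and Wipf1, beyond Gpr155, by 0.31 and 0.22. These genes were picked after their values were seen.

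RNA quality was read from control probe sets at the ends of the Gapdh and Actb transcripts. The log2 difference of 3' over 5' Gapdh controls was -0.18 ± 0.04 in knockout and -0.14 ± 0.03 in wildtype (n = 3 each, two-sided exact permutation p = 0.3), and that of Actb 0.40 ± 0.03 and 0.42 ± 0.000697 (exact permutation p = 0.4). Both had a Benjamini-Hochberg adjusted p of 0.4 over the 2 tests, and 3 arrays against 3 allow no p below 0.1.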

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

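Of the tests in this part, the counts over other splits of the arrays without the trend and for gene lists, the Xist covariate without the trend and the gene window without the trend were set before their results were seen. All the others were chosen after.

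The first pattern is the level of liver and erythroid transcripts, from marker lists fixed before the data were examined, with Afp at 13.28 and Alb at 13.16 in knockout. Probe set names paired with the wrong values are argued against by the ribosomal protein list, at the 99.82th percentile. Heart tissue with liver or blood carried over and arrays of another tissue under heart labels both stay open. The group differences given above therefore cannot be assigned to heart tissue. The liver list lay at the 98.3th percentile, and no lower than the 97.9th in any array. The sarcomere list lay at the 39.15th, with 22 of its 27 genes below the 50th, and between the 27.8th and 44.2th over the arrays. Of the sarcomere members, Myh6 lay at the 11.4th, Myl2 at the 20.2th, Tnni3 at the 20.6th and Myh7 at the 29.3th. Only Tpm1 and Actc1 lay above the 75th. No heart or liver array was analysed here to show where these lists lie in either tissue, and probe set sequence affects such levels. Other embryonic tissues that make Afp, Ttr and apolipoproteins stay open too.

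Y-linked and Xist transcripts in the same array are the second pattern: knockout c held the Y-linked Eif2s3y at 6.636 together with Xist at 11.25 at its brightest probe set, and wildtype a held Xist at 11.27 with Eif2s3y at 1.34. Background of the probe sets is argued against by the median of 3.751 log2 units by which knockout c lay above wildtype a over 7 Y-linked probe sets; the other 2 annotated, left out because knockout a and b did not both lie over 2 units above wildtype a there, were at -2.33 and 1.01, and the median over all 9 was 3.00. Wildtype tissue as the male part of a mixture stays undecided: 7 probe sets called without knockout c lay a median of 0.2806 log2 units from the diluted value on the knockout side, but 2 lay within their own gap between knockout a and b, a gap kept small by the choice of probe sets, and in knockout c the 4 lower ones lay toward wildtype and the 3 higher ones away from it. RNA of female and male tissue in 1 sample stays open: the Y-linked level was a median of 46.85% of knockout a and b, but only 5 of the 7 Y-linked probe sets lay below each of the 4 arrays without high Xist. Xist itself showed no dilution in knockout c beside wildtype a, the only other array with high Xist. Its other probe sets were at 10.55 and 7.72 in knockout c and 10.63 and 7.42 in wildtype a. No biological explanation was tested.

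Called genes near Sp3 form the third pattern. Without the trend 0 genes were called there, which decides nothing. With it and 1 probe set per gene Fisher's exact p was 0.06131, so a passenger genome of the targeted cells stays undecided, and the rules for a called gene that gave a p of 0.000882 and 0.0355 were chosen after the data were seen, the first adding Itga6 by 1 of its 2 probe sets. For the integrin probe sets a change in 1 part of the transcript or under 1 probe set may account for the calls, since the called Itga4 probe set differed from the gene's others by 1.907 log2 units and that of Itga6 by -1.084. An effect of the lost Sp3 on its neighbours goes with the genotype and was not tested.

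The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. Without the trend the real split gave 0 probe sets and 10 of 10 splits gave as many, the highest other 2. With the trend the real split gave 14 and the highest other 89, 2 of 10 giving as many, and for gene lists the real split gave 14 and the highest other 16, again 2 of 10. The split with 89 parted knockout a, knockout c and wildtype c from the rest. These 3 arrays also lay low on the interferon list, at -0.81, -0.94 and -0.87, against 0.80 to 1.21 in the others. Whether that response accounts for the 89 calls was not tested. The share of splits may therefore not reflect chance alone. With the Xist level as a covariate 0 probe sets were called without the trend and 10 with it. Xist levels overlap between the groups, which argues against embryo sex as the whole of the trend calls and leaves the count without the trend undecided.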

How the results depend on the processing

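Adding 16 intensity units, the interferon covariate, the gene windows and rules of the trend calls near Sp3 and all alternatives of the trend fit were chosen after the data were seen, and the rest before. Of 1615 values of named probe sets under an alternative, 1580 kept their direction and side of the threshold, 13 passed newly and 22 turned direction. Of 551 values of gene lists, 449 kept both, 27 passed newly, 61 lost the call, and in 14 the direction of the test turned. Sp3 was at -1.273 in the trend fit with adjusted p = 0.00254, against 0.133 to 0.705 in the other fits. Without the trend 0 probe sets were called under the other alternatives, except 1 higher with 16 intensity units added; the trend gave 7 higher and 7 lower. From there, array weights gave 18 lower, the Xist level as a covariate 4 lower, the interferon covariate 35 lower, and counting genes 4 higher and 11 lower. Leaving out 1 array gave 3 to 12 higher and 0 to 12 lower. The letter as a replicate block gave 52 higher and 206 lower. The letters are not said to mark litters, so they were not taken to pair the samples. Residuals of same-lettered arrays a, b and c correlated at 0.01, 0.308 and 0.436. Those of b and c were the highest of any knockout and wildtype pair, while knockout a did not correlate best with its own letter. Residuals within a group sum to 0, so these values do not decide whether the letters pair the samples. The number of lists called was 8 after quantile normalization, 8 with the mean of a gene's probe sets, 0 with an estimated correlation, 0 with fry, and 7 to 16 with 1 array left out. The odds ratio near Sp3, 17.2, was 0 with 50 genes on either side, which hold 0 called genes, 9.24 with 200, 56.4 with any probe set of a gene counted and 31.9 with the gene's probe set of highest mean in the fit of all probe sets; the last 2 passed. With the dimmer 50% of the probe sets left out the trend fit called 6 higher and 6 lower, and without the trend 0. The cause was not tested for any of these.

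None of the values that turned direction was called. For gene lists it was the direction of the test that turned, and the medians given need not have. Quantile normalization gave Krt18 0.003999, Hbb-y 0.00887 and Pf4 0.06734. Median centring gave ribosomal proteins -0.08398, Hbb-bh1 -0.02389 and Afp -0.0705. Afp was at -0.004342 with array weights and at -0.0006684 with the interferon covariate. Cardiac stress genes were at 0.1071 with the replicate block and 0.141 with the interferon covariate. The mean of a gene's probe sets gave cardiac stress genes -0.02249, p53 targets -0.05855 and ribosomal proteins -0.002568, and fry gave p53 targets -0.07823 and ribosomal proteins -0.007808. With 1 array left out, cardiac stress genes ranged from -0.1032 to 0.2665, p53 targets from -0.1454 to 0.07003, ribosomal proteins from -0.03652 to 0.02326, Krt18 from -0.1819 to 0.07028 and Hbb-y from -0.03272 to 0.008847. Hbb-bh1 ranged from -0.08905 to 0.1695, Pf4 from -0.03698 to 0.03803, Spint2 from -0.3242 to 0.09273 and Afp from -0.01854 to 0.03677. Mylpf ranged from -0.2847 to 0.2593, Uty from -0.1845 to 1.456 and Eif2s3y from -0.6766 to 3.093.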

Other observations

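This part gives values only, and no test was run for it; the arrays and genes in it were picked after their values were seen.

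Genes of the interferon response, antiviral proteins induced by interferons, differed between arrays of the same genotype. The list level was 1.21 in knockout b, 0.80 in wildtype a and 1.07 in wildtype b, and -0.81 in knockout a, -0.94 in knockout c and -0.87 in wildtype c. Usp18, a protease of this response, was at 8.86 in knockout b and at 5.29 and 5.13 in knockout a and c. In wildtype a, b and c it was at 7.82, 8.27 and 5.17. Ifit1 was at 6.31 in knockout b and at 2.08 and 1.93 in knockout a and c.

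Adult beta globin Hbb-b2 was at 7.34 in knockout c and 8.79 in wildtype c, and between 9.97 and 10.81 in the other arrays. The embryonic globin Hbb-y was at 13.37 ± 0.04 in knockout and 13.38 ± 0.03 in wildtype. Mpo, a granule enzyme of myeloid cells, was at 10.36 ± 0.39 and 10.03 ± 0.18.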
